A study of Mus musculus with 5 samples.

How the data were processed

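Gene expression was measured by sequencing of RNA from mouse placentas at embryonic day 9.5. Per the labels' protocols, the maternal decidua was peeled away before RNA was taken, and libraries were made with a stranded total RNA kit. The labels place 2 libraries in the Usp22-/- group and 3 in the wild-type group, and the replicate numbers come from the sample titles. No source used here says whether a library came from a single placenta or a pool, or which libraries share a litter, so p-values measure only the spread between these samples, which may be partly technical.

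The deposited table gives one value per gene and library, and per the labels it holds DESeq counts. The unit is a normalised signal, namely read counts that the authors divided by a size factor per library. This was found from the values. In each library every value above 0 is a whole multiple of the smallest one within a tolerance of 1e-06 (100% of values), and that smallest value differs between libraries, from 0.657 to 1.24. It was taken as the value of 1 read. In Usp22-/- replicate 1 it is 1.01, so close to 1 that an automatic check of steps could not tell it from rounding, but its values carry many decimals and are multiples of it like those of the other libraries. The implied size factors are 0.993 and 0.861 for Usp22-/- replicates 1 and 2 and 0.808, 1.52 and 0.962 for wild-type replicates 1, 2 and 3, and they equal the median-of-ratios factors computed from the recovered reads. CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.0 and DESeq 1.18.0 and the genome build mm10 are named, without their roles, per the submitters' processing notes. The gene annotation, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Overlapping and antisense genes and near-identical copies are therefore uncertain.

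Library totals were 19771299 and 17108344 reads in Usp22-/- replicates 1 and 2, and 16599085, 31994841 and 20255330 in wild-type replicates 1, 2 and 3. Wild-type replicate 2 was the deepest, with 18 of 15936 genes at 0. Depth alone did not set that number, which was 39 in wild-type replicate 3, 251 and 285 in Usp22-/- replicates 1 and 2, and 254 in wild-type replicate 1. Size factors assume that most genes do not differ between libraries, so a change in the amount of RNA per cell would not be seen. No pair of libraries was a duplicate: chi-square over degrees of freedom of their reads ranged from 25.0 to 218, and Pearson's r across genes, which are not independent replicates, from 0.861 to 0.989. For wild-type replicate 1, r was 0.942 and 0.968 with Usp22-/- replicates 1 and 2. It was 0.952 and 0.927 with wild-type replicates 2 and 3, so by r this library was closest to Usp22-/- replicate 2. By chi-square over degrees of freedom it was closest to wild-type replicate 2, at 57.0 against 61.7 with Usp22-/- replicate 2.

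Before the data were examined, edgeR's quasi-likelihood test was written as the main test for raw counts, with limma for the case that the table held counts divided by size factors. The second case applied. limma 3.58.1 in R 4.3.3 was run on log2(value + 1) with a trended prior variance, keeping 14953 genes with a value of at least 10 in at least 2 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate the change of low genes. All 5 libraries entered the fit, with genotype as the only term. Means are given with the SD over 2 Usp22-/- and 3 wild-type libraries, and log2 fold changes with the standard error of the fit.

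Lists of genes, 34 in number, were written before the data were examined and cover cell types that a dissected placenta could hold, signalling pathways, stress responses, the SAGA complex and housekeeping families. Members missing from the table were looked up under older symbols, which found 3. Of the lists, 32 had at least 3 tested members, and 2 (adult beta globins and mitochondrially encoded genes) had none in the table. Each list was tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, each adjusted over the 32 lists. Members were counted past the threshold over all genes and adjusted over the list alone.

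Genes were named by a rule fixed before the data were examined. It took Usp22, then the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 100 in the higher group and no overlap between groups, skipping predicted genes. From each list it took up to 4 members past the threshold with the smallest p, or up to 2 where none passed, and it took 5 sex-linked genes per library. Other genes named were chosen after their values were seen: Usp27x, Usp51, Kdr, Tek, Pdgfrb, Pecam1, Gzmd, Prl8a2, Tpbpa and Prl3b1, and in the additional observations Star, Cyp11a1, Cyp17a1, Hsd3b6, Hsd3b1, Meg3, Rian, Mirg, Dlk1, Rtl1 and Dio3. H19 and Apob were named for holding the most reads. The rule took 90 genes. Gene positions come from the GENCODE vM21 annotation of the same build, matched by symbol for 14239 tested genes.

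The steps were tested on simulated reads for the same 14953 genes and 5 libraries, in 5 runs, with known changes planted. At the trended dispersion of these data the test recovered 28.5% of 2-fold, 76.8% of 4-fold, 98% of 8-fold and 99.6% of 32-fold changes, with 31 false calls over the runs, and called 0 of 150 unchanged lists. Simulated genes varied independently, and the unchanged lists held random genes. The runs therefore cannot show false calls that arise where genes move together.

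Alternatives were pseudocounts of 0.5 and 8, no filter and a mean of 100, robust variances, TMM and quantile scaling, the replicate number as a block, and each library left out. On the recovered reads, edgeR 4.0.16 (quasi-likelihood with TMM, relative log expression or upper-quartile scaling, and the exact test), limma-voom and DESeq2 1.42.0 were run. A fit with wild-type replicate 1 as the only control, and a fit with the mean level of the natural killer list as a covariate, were added after the data were seen. The first of these has a single control library, so its spread between samples comes from the Usp22-/- libraries alone. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.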

Results

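RNA from mouse placentas at embryonic day 9.5 was sequenced in 5 libraries, of which 2 came from Usp22-/- and 3 from wild-type conceptuses. Usp22 encodes the ubiquitin protease of the SAGA coactivator complex, which removes ubiquitin from histones. The deposited table listed 15936 genes. The read total was 19771299 and 17108344 in Usp22-/- replicates 1 and 2, and 16599085, 31994841 and 20255330 in wild-type replicates 1, 2 and 3. The imprinted RNA H19 held the most reads in 4 of the libraries, at 1.03% to 1.31% of the total, and Apob held the most in Usp22-/- replicate 2, at 1.26%. Levels below are read counts divided by the library's size factor, called normalised reads, and log2 fold changes were fitted on log2(normalised reads + 1).

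The targeted gene was measured before the others. Usp22, on the minus strand of chromosome 11 at 61151785 to 61175055 of mm10, held 40.3 and 23.2 normalised reads in the Usp22-/- libraries, a mean of 31.8 ± 12.1 (SD, n = 2). In the wild-type libraries its mean was 3652 ± 166 (SD, n = 3). Usp22 fell by 6.85 on the log2 scale (SE 0.24, limma, adjusted p = 0.0075). The adjusted p was 0.144 without wild-type replicate 2, where the log2 fold change was -6.88. Among 25 measured genes of the SAGA list only Usp22 passed by limma, over all genes and adjusted over the list alone, and the list did not (camera adjusted p = 0.842). The edgeR quasi-likelihood test and limma-voom called 0 members higher and 1 lower, the exact test 1 and 1, and DESeq2 3 and 2. Usp27x and Usp51, which are counted in that list, encode proteases related to Usp22. Their log2 fold changes were -0.02 (SE 0.13) and 1.13 (SE 0.29, adjusted p = 0.067), and neither passed.

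The comparison of Usp22-/- with wild-type placenta asked which transcripts depend on Usp22 while placental vessels form. Prolactin-family genes made up 5 of the 10 largest decreases, and the largest increases included the plasma proteins Apoa4 and Plg. Cts7, a placental cathepsin, fell by 6.82 (SE 0.95) on the log2 scale. Ceacam15, of the placental carcinoembryonic antigen family, fell by 6.66 (SE 0.64), and Prl8a1, of the prolactin family, fell by 6.53 (SE 0.29, adjusted p = 0.0133). Prl3d3, Prl7a1, Prl3d2 and Prl2c2 fell too, with log2 fold changes of -6.29, -6.13, -6.10 and -5.46. The other decreases among the 10 largest were Usp22, Slc6a12, a betaine and GABA transporter, at -6.13 (SE 0.84), and Scin, an actin-severing protein, at -5.45 (SE 0.58).

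Increases were smaller than decreases at the extremes. Alox12b, an epidermal lipoxygenase, rose from 10.1 ± 3.12 to 132 ± 30.2 normalised reads, a log2 fold change of 3.60 (SE 0.39, adjusted p = 0.0365), and lies on chromosome 11 at 69156989, within 10 Mb of Usp22. Ttll10, of the tubulin ligase family, rose by 2.62 (SE 0.44), and Mpo, the peroxidase of myeloid granules, rose by 2.50 (SE 0.23). The microRNA gene Mir3070b rose by 2.41 (SE 0.45). Col8a2, a short-chain collagen, Rims2, a protein of vesicle release, and Apoa4, an apolipoprotein, rose by 2.27, 2.06 and 2.01. Slc22a8, an organic anion transporter, Plg, which encodes plasminogen, and Csf2rb, a receptor chain for myeloid growth factors, rose by 1.97, 1.95 and 1.94. In each direction 1 predicted gene ranked among these and was not named.

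**Figure D1:**
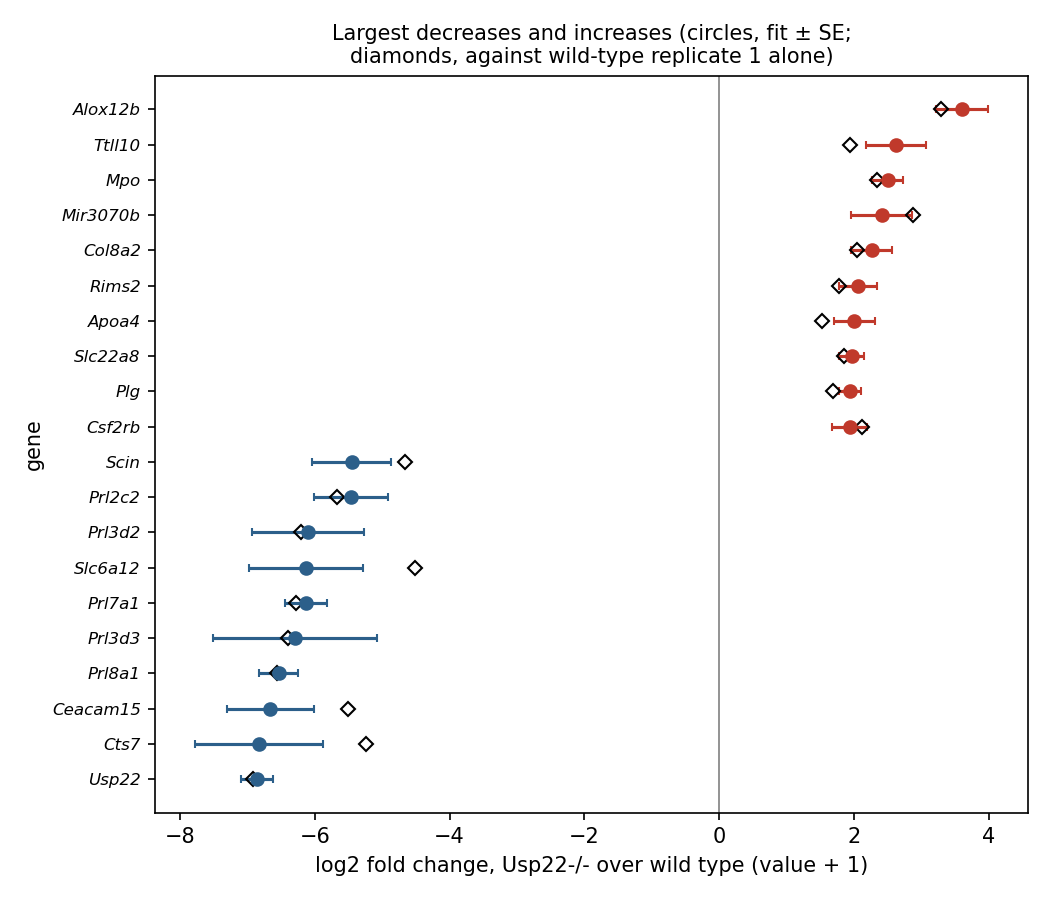
Log2 fold change of the named genes with the largest decreases and increases (x axis, Usp22-/- over wild type on log2(normalised reads + 1)), circles with bars for the fit and its SE, diamonds for the difference from wild-type replicate 1 alone. Usp22 sits at -6.85 and Alox12b at 3.60. Each diamond lies on the same side of 0 as its circle, which the rule of no overlap between groups fixed in advance.

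Over 14953 tested genes, 1034 passed an adjusted p of 0.05, 488 higher and 546 lower in Usp22-/- placenta, and 607 of them changed at least 2-fold (283 higher, 324 lower). The split was 584 higher and 415 lower with upper-quartile scaling in edgeR, 41 and 522 without Usp22-/- replicate 2, and 1 and 35 with the replicate number as a block. The groups did not overlap for 8453 tested genes (56.5%), and 886 of the 1034 calls had an adjusted p above 0.04. Chance gives 20% where genes are independent, and genes that move together can far exceed it in a single grouping of the libraries. The count rested on single libraries: it was 1 without Usp22-/- replicate 1, 563 without Usp22-/- replicate 2, 4765 without wild-type replicate 1, 0 without wild-type replicate 2 (3052 genes at unadjusted p below 0.05, limma) and 4 without wild-type replicate 3. The 2-fold count was 2724, 0 and 4 without wild-type replicates 1, 2 and 3. On the recovered reads, edgeR's quasi-likelihood test called 513 genes and DESeq2 4464.

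Libraries differed in maternal and sex-linked transcripts within as well as between genotypes. Genes of uterine natural killer cells, the granzyme-rich lymphocytes of the decidua, had a median log2 difference of -5.90 between wild-type replicate 1 and replicates 2 and 3 (14 genes). Gzmd, which encodes a granzyme, held 81.6 and 109 normalised reads in the Usp22-/- libraries and 295, 13334 and 27009 in wild-type replicates 1, 2 and 3. Prl8a2, a decidual prolactin, held 73.5 and 23.2 normalised reads in Usp22-/- and 592, 6076 and 9993 in wild type. The Y-linked gene Ddx3y held 2258 and 2426 normalised reads in Usp22-/-, 2400 and 1960 in wild-type replicates 2 and 3, and 3.71 in wild-type replicate 1. Eif2s3y, Kdm5d and Uty, also Y-linked, held 1.24, 0 and 4.95 normalised reads in wild-type replicate 1 and at least 451 in each of the other libraries. Xist, the RNA of the inactive X chromosome, held 46.3 and 37.2 normalised reads in Usp22-/- and 6038, 715 and 1459 in wild type. It passed as lower, at -5.44 (SE 0.89, limma, adjusted p = 0.0441). Xist was highest in wild-type replicate 1, the library without Y-linked transcripts, and rose from replicate 2 to 3 as Gzmd did. Its difference therefore cannot be told apart from the sex and maternal RNA of the libraries, and is not evidence of an effect of Usp22. Median differences from wild-type replicate 1 alone are therefore given beside many of the gene groups. Of the called genes, 409 of the 488 higher and 458 of the 546 lower differed at least 1.5-fold from that library in the same direction, and 190 and 290 did so at least 2-fold. The groups of all 1034 called genes did not overlap, so that direction was fixed in advance. Wild-type replicate 1 was also part of the fit that made the calls, so these counts are not independent support for them.

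**Figure D2:**
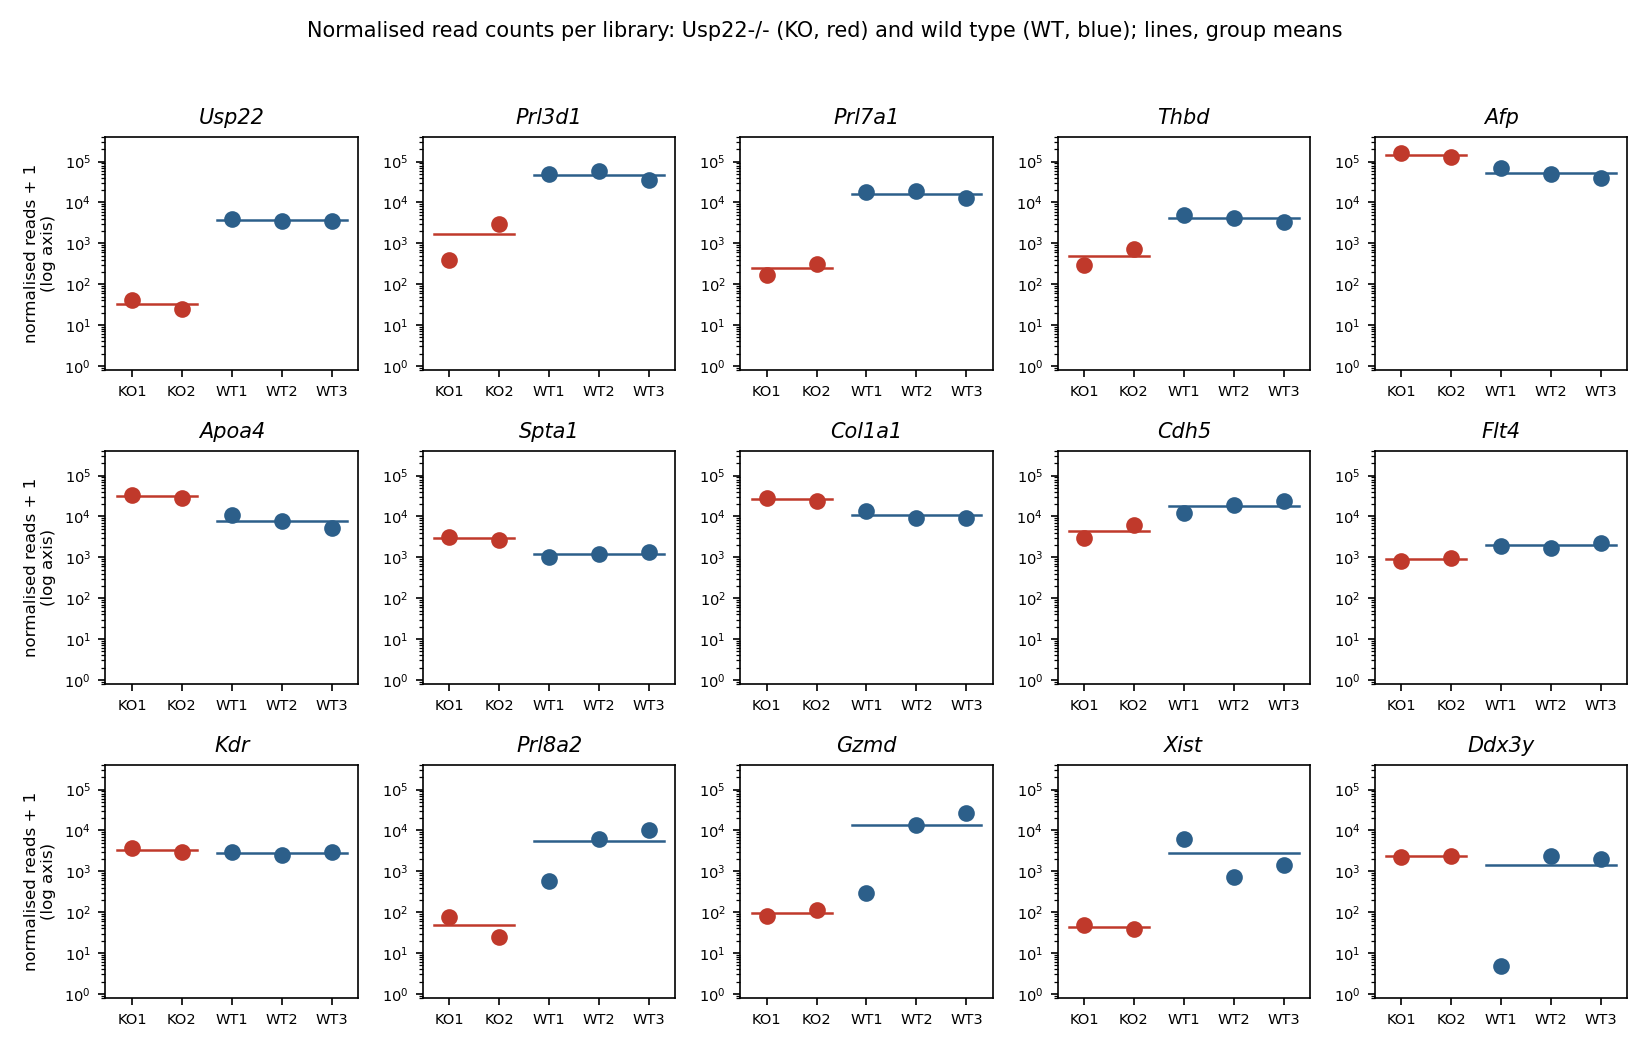
Normalised reads + 1 (log axis) per library for 15 genes, with Usp22-/- in red, wild type in blue and lines at the group means. Prl3d1 and Prl7a1 are low in both Usp22-/- libraries against all 3 wild-type libraries, whereas Gzmd and Prl8a2 are also low in wild-type replicate 1.

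Markers of parietal trophoblast giant cells, which border the decidua and secrete placental lactogens, were far lower in Usp22-/- placenta. Of 8 tested, 5 fell and none rose over all genes, and all 8 fell when adjusted over the list alone. Their median log2 fold change was -5.50, and -5.60 against wild-type replicate 1. Prl3d1, placental lactogen I, held 391 and 2977 normalised reads in Usp22-/- and 50370, 57871 and 36151 in wild type, a log2 fold change of -5.45 (SE 0.85, adjusted p = 0.0424). Prl7a1 dropped from 16565 ± 3084 to 244 ± 107 normalised reads (adjusted p = 0.0182). The list was lower by camera (adjusted p = 5.28e-06), a call not kept with an adjusted p = 0.73 with an estimated correlation. Prl3d1, Prl3d2 and Prl3d3, and Prl2c2 and its neighbours, are near-identical copies whose reads the counting could have divided between them. Apart from Prl2c2 at 12996125 to 13005383, the Prl genes named lie on chromosome 13 between 27094190 and 28151611.

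Other trophoblast groups had lower medians, with few members past the test over all genes. Among 16 spongiotrophoblast and glycogen trophoblast genes, 3 fell and none rose, and 10 fell when adjusted over the list alone. Prl8a9 and Prl5a1, both of the prolactin family, had log2 fold changes of -4.97 (SE 0.47) and -5.38 (SE 0.76). Prl7a2 held 0 and 1.16 normalised reads in Usp22-/- and 49.5 ± 37.0 in wild type (adjusted p = 0.0491). Tpbpa, a spongiotrophoblast marker, did not pass, at 35.3 and 1634 normalised reads in Usp22-/- and 1572, 23664 and 15107 in wild type (adjusted p = 0.131). Prl3b1, placental lactogen II, belongs to the list of sinusoidal giant cells and placental cathepsins below. Its groups overlapped likewise, at 28.2 and 422.7 normalised reads in Usp22-/- and 422.0, 10374 and 9978 in wild type (limma, adjusted p = 0.124). The list median was -4.62, and -2.24 against wild-type replicate 1 (camera adjusted p = 1.21e-05, and adjusted p = 0.73 with an estimated correlation). Of 4 genes of sinusoidal giant cells and placental cathepsins, 0 passed over all genes by limma, 4 had an unadjusted p below 0.05 and 4 fell when adjusted over the list alone. By edgeR's quasi-likelihood test and limma-voom 0 of them passed, and by the exact test and DESeq2 3 fell. Their median was -4.75, and -2.71 against wild-type replicate 1. Ctsq and Ctsj, placental cathepsins, stood at -4.54 (adjusted p = 0.0659) and -4.97 (adjusted p = 0.0724). That list's camera adjusted p was 0.0352, and it was 0.73 with an estimated correlation and 0.0543 without wild-type replicate 3.

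Progenitor and syncytial trophoblast lists did not pass as lists. Of 13 genes of trophoblast stem cells and labyrinth progenitors, 2 fell, and 4 fell when adjusted over the list alone (camera adjusted p = 0.096). They were Eomes, a transcription factor of trophoblast stem cells, at -3.29 (SE 0.53), and Ets2, at -0.95 (SE 0.19). Against wild-type replicate 1 they differed by -2.29 and -0.65. Eomes held 168, 413 and 561 normalised reads in wild-type replicates 1, 2 and 3, the order in which natural killer genes rose, so its decrease may in part follow maternal RNA. The list median was -0.50, and -0.16 against wild-type replicate 1. Of 12 syncytiotrophoblast genes, Gcgr, the glucagon receptor, rose by 0.86 (SE 0.14), also when adjusted over the list alone, and no other passed by limma. By DESeq2 1 rose and 2 fell, and by the quasi-likelihood test, the exact test and limma-voom 1 rose and 0 fell. The syncytiotrophoblast list median was -0.98, and -0.91 against wild-type replicate 1 (camera adjusted p = 0.096). Most of it came from 1 library: the median difference from the wild-type mean was -1.56 in Usp22-/- replicate 1 and -0.30 in replicate 2.

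Yolk sac visceral endoderm genes, many of them for plasma proteins and nutrient uptake, rose in Usp22-/- samples. Of 17 tested, 9 rose and none fell over all genes, and 17 rose when adjusted over the list alone. Afp, alpha-fetoprotein, rose from 52967 ± 15395 to 148534 ± 22513 normalised reads, a log2 fold change of 1.52 (SE 0.26, adjusted p = 0.0444). Cubn, the cubilin receptor of endocytosis, rose by 1.49 (SE 0.26), and Fgg, a fibrinogen chain, by 1.43 (SE 0.24). The list median was 1.40, and 0.90 against wild-type replicate 1 (camera adjusted p = 7.35e-08, and adjusted p = 0.73 with an estimated correlation). Of 12 parietal endoderm genes, Thbd, which encodes thrombomodulin, fell by 3.15 (SE 0.40) and was the only one to pass over all genes by limma. Adjusted over the list alone, 1 rose and 1 fell. The list did not pass (camera adjusted p = 0.842).

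Genes of primitive red cells rose too. Of 16 tested, 4 rose over all genes and 16 rose when adjusted over the list alone, with a median log2 fold change of 0.94, and 1.13 against wild-type replicate 1. Spta1 and Sptb, the spectrins of the red cell skeleton, rose by 1.29 (SE 0.15) and 1.04 (SE 0.16). Kel, a blood group antigen, and Klf1, the erythroid transcription factor, rose by 1.39 (SE 0.18) and 0.93 (SE 0.18). The camera adjusted p was 2.50e-07, and the list had an adjusted p = 0.73 with an estimated correlation.

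**Figure D3:**
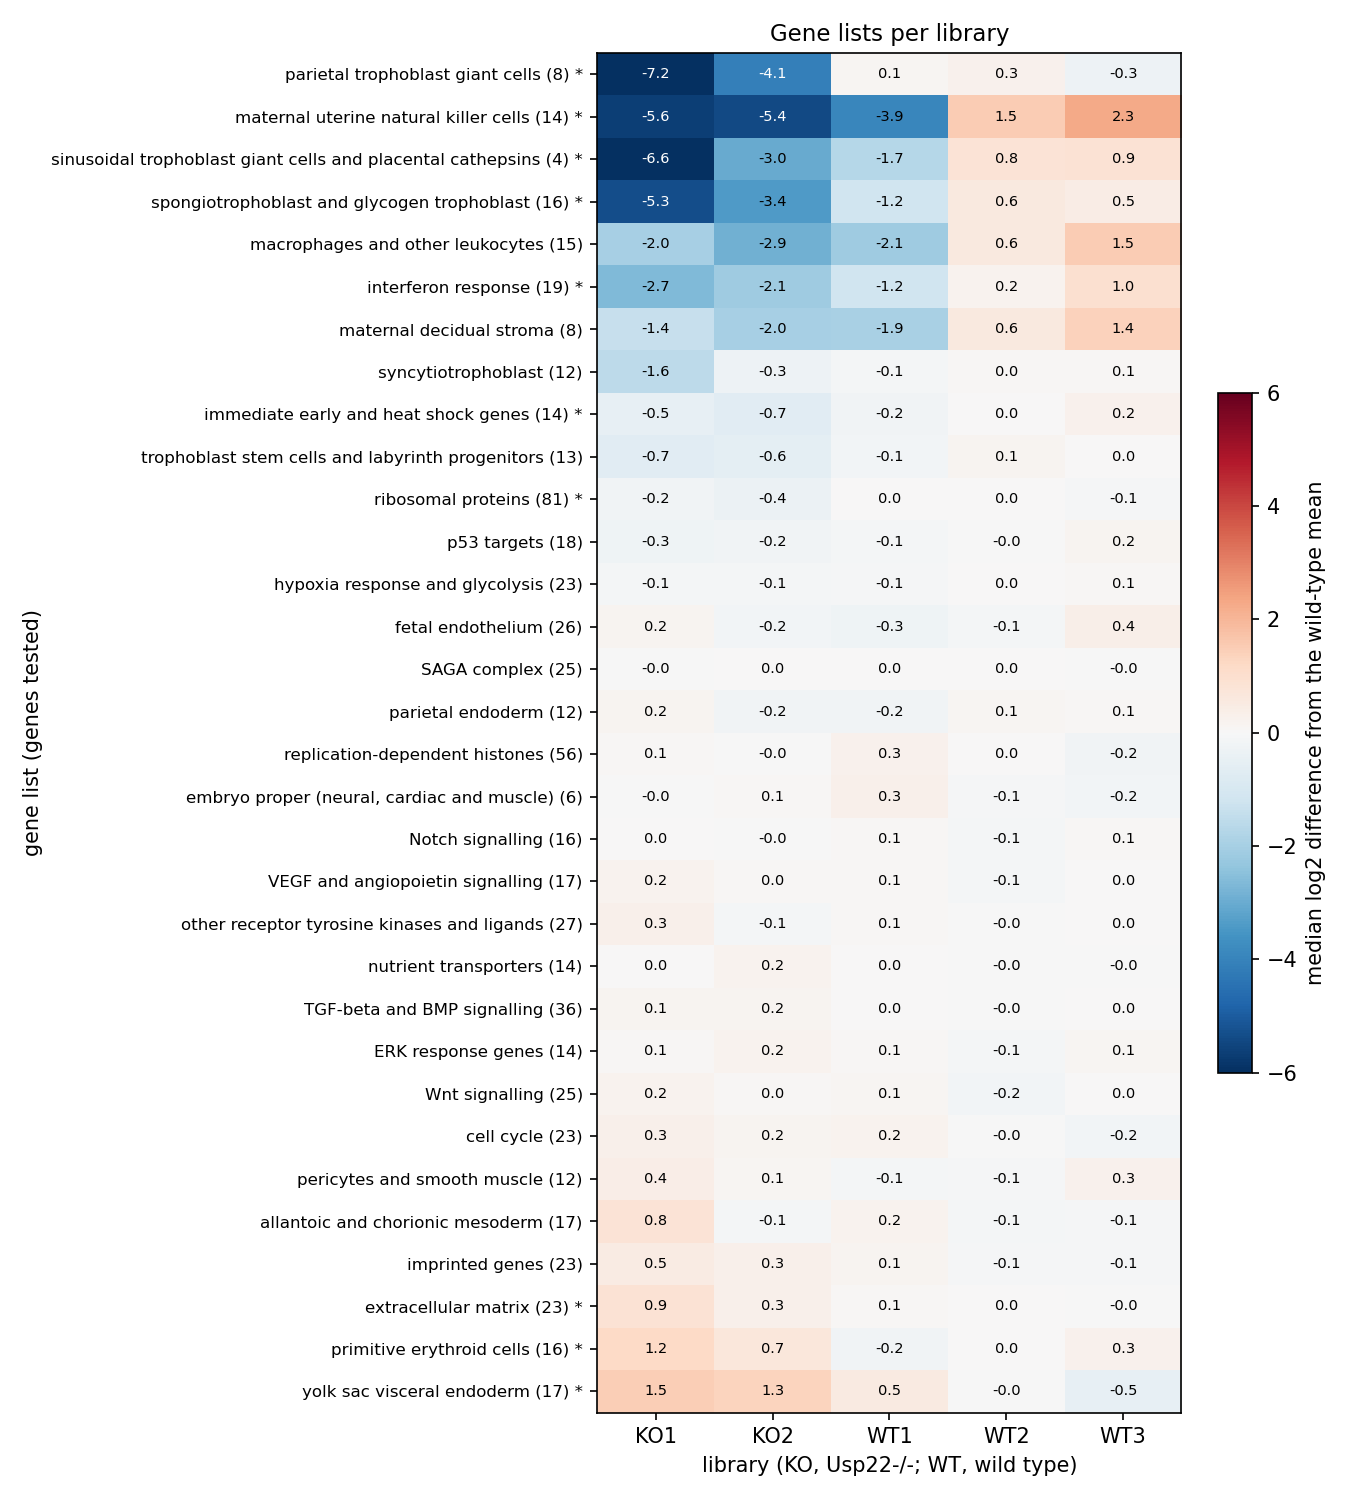
Median log2 difference of each gene list from the wild-type mean (colour and number) per library, with the number of tested genes in brackets and an asterisk on the 10 lists that passed camera with a preset correlation. Parietal giant cell genes stand at -7.16 and -4.08 in the Usp22-/- libraries and within 0.3 of 0 in wild type, and natural killer genes at -3.93 in wild-type replicate 1.

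Endothelial and mural genes moved little as groups. Of 26 fetal endothelial genes, 3 fell over all genes and the same number when adjusted over the list alone, and the list median was -0.02, and 0.18 against wild-type replicate 1 (camera adjusted p = 0.867). Cdh5, which encodes VE-cadherin, fell by 2.08 (SE 0.42, adjusted p = 0.0499). Esam, a junction protein, and Flt4, the receptor of VEGF-C, fell as well, at -1.91 (SE 0.26) and -1.13 (SE 0.15). Against wild-type replicate 1 these 3 differences were -1.53, -1.75 and -1.08. Kdr, the main VEGF receptor, had a log2 fold change of 0.25 (adjusted p = 0.22), Tek, the angiopoietin receptor, 0.41 (adjusted p = 0.15), and Pdgfrb, a pericyte receptor, -0.11 (adjusted p = 0.56). Pecam1 stood at -1.39 (adjusted p = 0.12). These 4 genes were chosen after their values were seen. Of 12 pericyte and smooth muscle genes, 0 passed over all genes or when adjusted over the list alone by limma, 3 had an unadjusted p below 0.05, and edgeR's quasi-likelihood test and limma-voom called 0. The edgeR exact test and DESeq2 each called 1 higher and 2 lower. Their median was 0.34, and 0.01 against wild-type replicate 1, their mean -0.28, and their camera adjusted p 0.822. Acta2, smooth muscle actin, stood at 1.04 (adjusted p = 0.0914) and Des, desmin, at -4.18 (adjusted p = 0.11), the latter -1.30 against wild-type replicate 1.

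Receptor and ligand groups for vessel growth gave single calls in both directions. Among 17 VEGF and angiopoietin genes, Flt4 and Pgf, the placental growth factor, fell, the latter at -1.87 (SE 0.32). Adjusted over the list alone 2 rose and 2 fell. Of 36 genes of TGF-beta and BMP signalling, 4 rose and 3 fell, and adjusted over the list alone 5 rose and 3 fell. They included Serpine1, the plasminogen activator inhibitor, at -4.14 (SE 0.67), the receptors Acvr1 at 0.70 and Acvrl1 at -0.66, and the signal transducer Smad1 at 0.66. Of 27 other receptor tyrosine kinase genes only Insr, the insulin receptor, passed by limma, at 0.64 (SE 0.11), and 5 rose and 3 fell when adjusted over the list alone. For these genes limma-voom called 3 higher and 1 lower, the exact test 4 and 3, DESeq2 7 and 4, and the quasi-likelihood test 0. Of 14 ERK response genes Fosl1, an AP-1 factor, fell by 3.85 (SE 0.61), and 1 rose and 1 fell when adjusted over the list alone. Of 25 Wnt genes Tcf7l2, a transcription factor of the pathway, rose from 265 ± 31.9 to 530 ± 76.2 normalised reads, alone also when adjusted over the list alone. Of 16 Notch genes 0 passed by limma, over all genes or adjusted over the list alone, with 4 at an unadjusted p below 0.05, and Dll4, an endothelial ligand, stood at -0.89 (adjusted p = 0.054) and Hey1, a target, at -0.43 (adjusted p = 0.126). The edgeR quasi-likelihood test and limma-voom called 0 Notch genes, and the exact test and DESeq2 called 2 lower. The camera adjusted p of these 6 lists lay between 0.401 and 0.963. Medians were above 0 and means below 0 in all of them, and camera's direction followed the median except for the Notch list.

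Matrix and mesoderm genes were higher in part. Of 23 extracellular matrix genes 4 rose, and 11 rose when adjusted over the list alone, with a median of 0.57, and 0.69 against wild-type replicate 1. The median difference from the wild-type mean was 0.886 in Usp22-/- replicate 1 and 0.305 in replicate 2. Tnc, tenascin C, rose by 1.32 (SE 0.15), Col1a1 by 1.30 (SE 0.20), Col1a2 by 1.08 (SE 0.19) and Fn1, fibronectin, by 0.94 (SE 0.13). The camera adjusted p was 0.000916, and it was 0.73 with an estimated correlation and 0.0508 without wild-type replicate 1. Of 17 allantoic and chorionic mesoderm genes, Col1a1, Col1a2 and the transcription factor Tbx2, at 1.14 (SE 0.21), rose over all genes, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.205). The mesoderm median was 0.35, and -0.11 against wild-type replicate 1. It came from 1 library: the median difference from the wild-type mean was 0.80 in Usp22-/- replicate 1 and -0.095 in replicate 2.

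Maternal and immune lists had higher medians in wild-type replicates 2 and 3 than in the other libraries. Of 14 uterine natural killer genes 0 passed by limma over all genes or when adjusted over the list alone, although 10 had an unadjusted p below 0.05. The edgeR quasi-likelihood test and limma-voom also called 0 of them, and the exact test and DESeq2 called 11 lower. Their median was -5.42, unchanged with the 3 genes at 0 in both Usp22-/- libraries set to a floor of 3 reads over both, and -1.57 (SD 1.02) against wild-type replicate 1. Il2rb, a cytokine receptor chain, stood at -4.74 (adjusted p = 0.0559) and Gzme, a granzyme, at -5.70 (adjusted p = 0.105). The camera adjusted p was 0.000596, with an adjusted p = 0.784 with an estimated correlation. Of 19 interferon response genes 0 passed by limma, 9 had an unadjusted p below 0.05, and 7 fell when adjusted over the list alone. The quasi-likelihood test called 0 interferon genes, limma-voom 1, the exact test 12 and DESeq2 14, all lower. Bst2, tetherin, stood at -0.56 (adjusted p = 0.0545) and Oas1a at -3.36 (adjusted p = 0.0626). The interferon median was -2.23, and -0.19 against wild-type replicate 1 (camera adjusted p = 0.000889, and adjusted p = 0.794 with an estimated correlation). Of 15 leukocyte genes Csf1r, the macrophage growth factor receptor, fell by 2.37 (SE 0.38), and by 1.93 against wild-type replicate 1, alone also when adjusted over the list alone. The leukocyte median was -2.47, and 0.01 against wild-type replicate 1 (camera adjusted p = 0.096). Of 8 decidual stroma genes Zbtb16, a zinc finger repressor, rose by 1.16 (SE 0.18), and 1 rose and 1 fell when adjusted over the list alone, with a median of -1.68, and 0.01 against wild-type replicate 1 (camera adjusted p = 0.182).

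Housekeeping and stress groups shifted by smaller amounts. Of 81 ribosomal protein genes 2 fell, and 12 fell when adjusted over the list alone. Rps4l and Rps11 were the 2, at -0.73 and -0.44. The list median was -0.28, and -0.31 against wild-type replicate 1, with 80 of the 81 below 0 (camera adjusted p = 2.64e-12, and adjusted p = 0.73 with an estimated correlation). Of 14 immediate early and heat shock genes 3 fell, and 7 fell when adjusted over the list alone. They were the chaperone genes Hspa1b and Hspa1a, near-identical copies, at -2.59 (SE 0.36) and -2.66 (SE 0.38), and Junb, an AP-1 factor, at -1.51 (SE 0.22). That list had a median of -0.74, and -0.40 against wild-type replicate 1, a camera adjusted p of 0.00211, and an adjusted p = 0.73 with an estimated correlation.

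The remaining groups did not pass as lists. Of 23 hypoxia and glycolysis genes Adm, the vasodilator peptide adrenomedullin, fell by 3.76 (SE 0.51) and Higd1a fell by 0.63 (SE 0.11), and 1 rose and 6 fell when adjusted over the list alone. Of 23 imprinted genes 3 rose and 1 fell, and 8 rose and 3 fell when adjusted over the list alone. Kcnq1ot1 and Airn, long silencing RNAs, rose by 1.38 and 1.25, Plagl1 rose by 0.86, and Cdkn1c, a growth inhibitor of the Kcnq1ot1 domain, fell by 1.24 (SE 0.19). Among 14 nutrient transporters Abcg2, Slc7a8 and Slc40a1, the iron exporter, rose by 0.90, 0.77 and 0.60, and the amino acid transporter Slc38a4 fell by 0.85 (SE 0.10). Adjusted over the list alone 3 transporters rose and 4 fell. Of 23 cell cycle genes Mki67 rose by 0.94 and Cdc6, a replication licensing factor, fell by 0.53, both also when adjusted over the list alone, and the median was 0.24, and -0.04 against wild-type replicate 1. Of 56 histone genes, many of them near-identical, Hist1h1a fell by 0.68, and 0 passed when adjusted over the list alone. Of 18 p53 targets 0 passed by limma, over all genes or adjusted over the list alone, with 5 at an unadjusted p below 0.05. Bax, an effector of cell death, stood at -0.41 (adjusted p = 0.0509) and Phlda3 at -0.71 (adjusted p = 0.0705). The quasi-likelihood and exact tests called 0 p53 targets, limma-voom 1 and DESeq2 4, all lower. Of 6 genes of the embryo proper 0 passed over all genes by limma, 2 had an unadjusted p below 0.05, and 1 rose and 1 fell when adjusted over the list alone. The quasi-likelihood test called 0 of these, limma-voom 1 higher, and the exact test and DESeq2 1 in each direction. Tubb3, a neuronal tubulin, stood at -2.06 (adjusted p = 0.0629) and Tnni1, a troponin, at 1.41 (adjusted p = 0.0652). The camera adjusted p of these 7 lists lay between 0.055 and 0.963, and median and mean differed in sign for transporters and the embryo proper.

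In all, camera with a preset correlation of 0.01 called 10 of 32 lists, 3 higher and 7 lower, and 0 with an estimated correlation, where the smallest raw p was 0.0666 and 0 lists had an unadjusted p below 0.05. By fry, which asks whether a list's genes move one way on balance, 0 lists passed, with 11 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0858. The mixed fry test, which counts changes in either direction, passed 23 of the 32 lists. Its smallest adjusted p, 0.0043, was that of the SAGA list, where only Usp22 passed by limma. It also passed the Notch list (0.0126), where 0 genes passed by limma, so this count does not measure how many lists moved as groups.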

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

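The fits with wild-type replicate 1 as the only control and with the natural killer level as a covariate were chosen after the result was seen, and the other settings were planned. All called genes kept their direction in every setting that tested them, which the lack of overlap between their groups fixed for fits on fewer libraries. With single libraries left out, the count of changed genes ranged from 0 (without wild-type replicate 2) to 4765 (without wild-type replicate 1), and the count changed at least 2-fold from 0 to 2724 (same libraries). It was 1 without Usp22-/- replicate 1, 563 without Usp22-/- replicate 2 and 4 without wild-type replicate 3. Usp22 ranged from -7.24 (without Usp22-/- replicate 1) to -6.47 (without Usp22-/- replicate 2). It kept its call except without wild-type replicate 2 (-6.88, limma, adjusted p = 0.144) and with wild-type replicate 1 only (-6.92). The other fits that left out a single library kept the call. The adjusted p of Usp22 over settings with at least 2 libraries per group ran from 2.38e-196 (DESeq2) to 0.144 (limma, without wild-type replicate 2).

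Most fits on the recovered reads moved the counts by over 1.5 times, except limma-voom (1437) and upper-quartile edgeR (999). The edgeR quasi-likelihood test called 513 genes (334 at least 2-fold) with TMM, all among the 1034, 471 (319) with relative log expression factors, 541 (335) with robust variances and 515 (337) with no filter. The exact test called 2804 (1824) and DESeq2 4464 (1959). With wild-type replicate 1 only, 5 genes passed (5 at least 2-fold), and with the natural killer covariate 6 (6). Counts with other pseudocounts, filters and scalings, robust limma, limma-voom and upper-quartile edgeR lay between 941 and 1437, and the cause of the differences was not tested. The median of all genes moved by less than 0.1 under each scaling.

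No source used here says that libraries with the same replicate number share anything else. With 2 Usp22-/- libraries the deviations from their mean mirror each other, so the correlations below cannot settle it. Deviations of same-numbered libraries from their group means correlated at 0.0247 and 0.117 across genes, and a fit with the number as a replicate block called 36 genes (36 at least 2-fold), 26 of them among the 1034, with 1 residual degree of freedom.

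Between 8 and 14 lists were called in the 21 other settings of camera, and 0 with an estimated correlation and 0 by fry. Of the 10 lists, 6 were called in all 21. Sinusoidal giant cells lost the call in 6 (largest adjusted p 0.237), extracellular matrix without wild-type replicate 1 (0.0508), and natural killer cells with the covariate made from them (0.533). Interferon response lost it with the covariate, with its direction reversed (0.737, range over its settings 2.63e-06 to 0.737). It also lost it with wild-type replicate 1 only, where the control group was a single library. The cause was not tested. Of the 22 lists not called, 11 took the other direction and 8 were called in at least 1 setting. Depth limits genes near the filter of 10, and simulated 2-fold changes were recovered at 28.5%.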

Other observations

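The tests reported here were chosen after the result was seen, except that of genes near Usp22 and the count of other splits. Of the steroid-producing genes, 4 that fell in Usp22-/- placenta were chosen after their values were seen, and the group was not tested as a list. Star, the cholesterol carrier of mitochondria, held 429 and 1088 normalised reads in Usp22-/- and 27154, 22169 and 11798 in wild type, a log2 fold change of -4.81 (SE 0.52, limma, adjusted p = 0.037). Cyp11a1, which cleaves the cholesterol side chain, Cyp17a1, a hydroxylase of the androgen route, and Hsd3b6, a steroid dehydrogenase, stood at -4.91 (adjusted p = 0.038), -4.65 (adjusted p = 0.044) and -4.49 (adjusted p = 0.042). Hsd3b1, another steroid dehydrogenase, held 114 and 127 normalised reads in Usp22-/- and 106, 68.3 and 41.6 in wild type, at 0.83 (adjusted p = 0.214). The first 4 were lower in both Usp22-/- libraries than in each wild-type library, and their wild-type replicate 1 level was the highest of the wild-type libraries.

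RNAs of the imprinted Dlk1 to Dio3 region on chromosome 12 (109452823 to 110281097) were in large part higher in Usp22-/- samples. Of 48 tested genes 46 had a positive log2 fold change and 10 passed as higher, all microRNA genes, against 453 of 14191 genes elsewhere. The filter kept genes below 10 in every wild-type library only where both Usp22-/- libraries reached 10, which fixed their direction in advance. Mir431, a called gene of this kind, held 12.1 and 17.4 normalised reads in Usp22-/- and 1.24, 0.657 and 1.04 in wild type. Mir377, also called, did not depend on it, at 85.6 and 87.1 against 14.9, 28.9 and 23.9. The region was chosen after its RNAs were seen, so the odds ratio below restates the observation. It was 7.98 (95% interval 3.52 to 16.4, Fisher's exact test, two-sided, p = 2.59e-06), with the limit that these transcripts overlap and are not independent. Meg3, the long RNA of the region, held 13562 and 16342 normalised reads in Usp22-/- and 946, 3558 and 3117 in wild type, at 2.77 (adjusted p = 0.054). Rian and Mirg stood at 1.90 (limma, adjusted p = 0.102) and 1.97 (adjusted p = 0.0748), and none of these long RNAs passed. Of the protein-coding genes of the region, Dlk1 stood at 0.69 (adjusted p = 0.404), Rtl1 at -0.33 (adjusted p = 0.754) and Dio3 at -1.43 (adjusted p = 0.0829). Wild-type libraries differed here: Dlk1 held 7742, 2488 and 2320 normalised reads in replicates 1, 2 and 3, and Rtl1 1239, 267 and 300. Against wild-type replicate 1 Dlk1, Rtl1 and Meg3 differed by -0.44, -1.75 and 3.98. Against replicates 2 and 3 they differed by 1.25, 0.38 and 2.16. Why the RNAs differed was not tested.

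Parietal giant cell genes were low in both Usp22-/- libraries. Maternal tissue in wild-type replicates 2 and 3 is argued against, because the median difference from wild-type replicate 1, which had little of it, was -5.60 (SD 1.55 over 8 genes), and from replicate 2 to replicate 3 these genes fell by 0.498 while natural killer genes rose by 0.931. The sex of the sampled tissue is argued against by a median of -5.87 (SD 1.60) against wild-type replicates 2 and 3, which hold Y-linked transcripts as the Usp22-/- libraries do. Giant cells removed together with the decidua stay open. Wild-type replicate 1 kept them (0.148 above replicates 2 and 3) with little maternal RNA, but it is a single library, and the Usp22-/- maternal lists lay lower (natural killer, median -1.57 against it) or near it (decidual stroma 0.01, leukocytes 0.01, interferon -0.19), so dissection and loss of giant cells without Usp22 cannot be told apart.

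Yolk sac endoderm genes were higher in Usp22-/- samples. A lower share of trophoblast and maternal cells would raise all other fetal types alike, and stays open. There was a difference of 1.34 between the yolk sac median and that of 72 genes of endothelium, mural cells, mesoderm, parietal endoderm and embryo (permutation over genes, two-sided, p = 5e-05). It was 0.742 against wild-type replicate 1, where the SD of those 72 genes was 0.775. The permutation takes genes as independent units, although the estimated correlation among yolk sac genes was 0.956. Its p therefore does not measure the spread between libraries. Red cell genes rose too (median 0.94, and 1.13 against wild-type replicate 1). Maternal dilution of wild-type replicates 2 and 3 may add to the change and stays open, since the difference from wild-type replicate 1 was 0.904 (SD 0.277) but rests on that single library, and from wild-type replicate 2 to 3 these genes fell by 0.479 (SD 0.211) while natural killer genes rose. A larger share of yolk sac endoderm in the samples is consistent with 94.1% of members (16 of 17) lying within 0.5 of the list median, and whether it came from dissection or from the genotype was not tested.

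Maternal, interferon and leukocyte genes, 56 in all, had a median difference of -0.178 from wild-type replicate 1 and -4.05 from replicates 2 and 3, consistent with maternal tissue in those libraries as the source of most of the decrease. The natural killer genes were also lower than in wild-type replicate 1 (median -1.57, SD 1.02), and that part stays open with a single such library. Of the 56 genes, 37 held at least 10 normalised reads in both Usp22-/- libraries too, and 1 stands in another list. Gzmd held as much as 27009 normalised reads in wild-type replicate 3, and how far the peeling of the decidua reduced maternal transcripts was not tested. For Cdh5, Esam and Flt4 the medians were -1.53 and -1.99, and they rose by 0.312 from wild-type replicate 2 to 3. Vessels of maternal tissue may therefore account for part of their decrease, which cannot be told apart from a change in fetal endothelium with a single library low in maternal RNA. All 3 genes were lower in Usp22-/- replicate 1 than in replicate 2, as the parietal giant cell list was (medians -7.16 and -4.08). The fetal endothelial list was not (0.15 and -0.16). Whether cells other than endothelium held part of these transcripts was not tested.

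Genes within 10 Mb of Usp22 (chromosome 11, 51151785 to 71175055) were called no more often than others, at 14 of 267 against 984 of 13971 (odds ratio 0.73, 95% interval 0.392 to 1.25, Fisher's exact test, two-sided, p = 0.331), which argues against flanking DNA of another strain as the origin of many calls but says nothing of single genes such as Alox12b, which lies in that window. Of the 10 splits of the 5 libraries into 2 and 3, only the real split (1 of 10) gave as many as 1034 genes. The highest other split, wild-type replicates 2 and 3 against the rest, gave 976, and 805 at least 2-fold, against 607 for the real split. The remaining 8 gave 0 by limma. Those splits are too few for a share under 0.05, and the split with 976 calls parts the libraries by their level of natural killer transcripts.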
